A study of Arabidopsis thaliana with 6 samples.

How the data were processed

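The samples were whole seedlings of Arabidopsis thaliana Col-0 grown for 2 weeks on medium with 2 mM ethanol or without it, 3 samples per group, and the groups and replicate numbers were taken from the sample titles and treatment labels. Per the labels' protocols, total RNA was extracted from whole plants and 200 ng was labelled with Cy3 by a low-input amplification kit. Per the file headers, each array was a 1-colour Agilent array of a custom Arabidopsis design, and the scanner images were read with Feature Extraction 10.7.3.1. The deposited scanner files, 1 per array, hold spot intensity on a linear scale. Per the file headers, the processed intensity is the signal after the scanner software's background subtraction and detrending, not normalised between arrays, and the mean intensity and the median background intensity of each spot are given beside it. The deposited table of the authors' values is on a log2 scale. Its columns had nearly the same distribution, with medians between 5.59 and 5.60, and correlated at 0.996 to 0.999 with the log2 of the median spot signal of the same array. RMA and limma are named in the submitters' processing notes, with no role or version, and the exact steps behind that table are not given in the sources used here. The values were not centred on a reference, and the table holds single samples, so no direction had to be settled.

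For the values reported here, control spots and spots with an outlier flag were left out, log2 of the processed signal was taken, and the 75th percentile of each array over its non-control probes was subtracted. Spots of 1 probe were averaged. The 53459 non-control spots held 52586 probes. Of these, 32878 carry a gene ID in the array's design, for 32781 genes, and the symbols of genes were taken from the reference annotation of assembly TAIR10.1, where 32316 of those IDs were found. The file headers name a different genome build, so coordinates are not given. Where a list symbol differs from the reference symbol by more than a hyphen, a letter case or the species prefix At, both or the gene ID are given. A feature was tested if it was well above background on at least 3 of the 6 arrays, whatever their group. This left 27459 features, of which 21328 were genes with an ID and 6131 were probes without one, which were tested under the probe's ID and counted apart. Of several probes of a gene, that with the highest mean was used. In 95 genes with 2 measured probes, the differences of both probes had the same sign in 67 and a correlation of 0.65 across genes. There were 91 measured exon probes beside a gene's own probe, with the same sign in 60.

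Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided, no covariates), with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Differences are ethanol minus control on the log2 scale, with the standard error of the fit. A set of 29 gene lists with 559 different genes was fixed before the data were examined, of which 518 genes were measured. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists with at least 5 measured members, and with an estimated correlation and fry as alternatives. A count adjusted over the list alone is given beside the count over all genes. The rule for named genes was also fixed before the data were examined. It takes the 10 largest changes in each direction among genes that pass without overlap between arrays, filled up to 5 by the smallest p where fewer pass, every measured member of the ethanol list, the 4 members with the smallest p in the direction of each list that passes, and up to 2 members with the smallest p in each other list.

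Most alternatives changed 1 choice. Normexp correction with quantile scaling changed background and scaling together, and the authors' value table replaced signal, background and scaling at once. The alternatives were quantile, median and no scaling, normexp background correction (offset 50) with either scaling, the authors' value table, other background filters, the mean of a gene's probes, every probe on its own, other variance models, the replicate number or the slide as a block, each array left out in turn, and other thresholds. Camera takes no robust variance, so that setting was run for genes alone. Slide and scan were read from the files, which put replicates 1 and 2 of both groups on slide 1 and replicate 3 of both groups on slide 2, so the slide could be fitted as a block. On slide 2 each group had 1 array, so values from it have no test. No value of a feature was identical on 2 arrays.

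The test was checked on simulated data with the means and spread of the 27459 features. In 5 rounds, each with 200 changed genes, the share recovered was 48.8% at a log2 change of 0.5, 80.0% at 1, 90.8% at 1.5 and 98.4% at 2, with 64 false calls in all. Many changed genes ease the adjusted threshold, so these shares do not hold where few genes changed. In simulated lists of 20 independent genes, camera with the preset correlation recovered a shift of 0.15 in 5 of 5 rounds and called 0 of 245 unshifted lists, while camera with an estimated correlation recovered it in 0 of 5 rounds. Independent genes keep to the preset correlation by construction. In the data the estimated correlation ran from -0.02 (circadian clock) to 0.68 (jasmonate), with 0.34 for photosynthesis. The check thus does not bear on the preset p-values of lists whose genes vary together.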

Results

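Transcript levels were measured in whole seedlings of Arabidopsis thaliana, accession Col-0, grown for 2 weeks on MS medium, a mineral nutrient medium, that held either 2 mM ethanol or none. The plants grew at 22 °C in a cycle of 16 h light and 8 h dark and were collected at Zeitgeber time 5, that is 5 h after lights on. The comparison asks how the transcriptome of seedlings raised on ethanol differed from that of control seedlings. Each group had 3 arrays, and each array was a 1-colour Agilent array hybridised with Cy3-labelled RNA of 1 sample. The labels do not say whether the 3 samples of a group were grown separately. The p-values of single genes thus measure the spread between these samples, which may be technical. Those of gene lists with the preset inter-gene correlation of 0.01 rest mainly on the spread across genes, taken as nearly independent. On each array, 53459 spots carried probes other than controls. Between 27184 and 29424 of them, or 50.9% to 55.0%, were well above background, and none were saturated. The 75th percentile of the processed signal was 359.3, 350.1 and 296.3 on the control arrays and 405.4, 437.2 and 313.8 on the ethanol arrays. The number of arrays limits the precision of every value below. Replicates 1 and 2 of both groups lay on slide 1 and replicate 3 of both groups on slide 2.

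The 6 arrays were closely alike. Pearson correlations across the 27459 measured features ranged from 0.989 between control replicates 1 and 3 to 0.994 between ethanol replicates 1 and 2. The components with the most variance did not part the groups. Component 1, with 32.0% of the variance, ran from control replicate 1 to control replicate 3, and component 2, with 22.3%, set ethanol replicate 3 apart from the rest. Component 3, with 19.6%, placed the 3 control arrays between 7.88 and 16.1 and the 3 ethanol arrays between -25.6 and 0.781.

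No gene passed the test between ethanol-grown and control seedlings. The genes with the smallest p-values included GolS2 and PUB19 among those that were lower and the cell wall genes BXL2 and GH9B13 among those that were higher. GolS2 (AT1G56600), a galactinol synthase of the raffinose pathway, was lower by a log2 difference of -1.16 ± 0.13 (SE, n = 3 per group), or 2.23-fold, and PUB19 (AT1G60190), a U-box ubiquitin ligase, by -0.86 ± 0.08. AT4G21930, the cytochrome P450 gene CYP706A6 (AT4G12320) and AT1G24148 followed at -0.69 ± 0.08, -0.46 ± 0.05 and -0.55 ± 0.06. Among the genes that were higher, AT1G26250 had a difference of 0.61 ± 0.07, BXL2 (AT1G02640), a beta-xylosidase, 0.49 ± 0.08, and GH9B13 (AT4G02290), a glycosyl hydrolase, 0.32 ± 0.05. The resistance gene WRR4 (AT1G56510) and AT2G30540 differed by 0.42 ± 0.07 and 0.32 ± 0.05. In each of these 10 genes the 3 ethanol arrays lay on one side of the 3 control arrays, and the direction was the same on both slides. The genes were picked by p over these same arrays, which favours both outcomes. Neither outcome is thus an independent check of the differences. For GolS2 the difference was -1.20 on slide 1 and -1.06 on slide 2, and for PUB19 it was -0.90 and -0.78.

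In limma, 0 of 27459 features differed at an adjusted p under 0.05, among them 0 of the 21328 genes with a gene ID. The lowest adjusted p, 0.0728, was shared by 6 of the 10 genes above. At an unadjusted p under 0.05 there were 1834 features, where 1373 would be expected by chance, with 810 higher and 1024 lower in ethanol-grown plants. Of the genes with an ID, 744 were higher and 696 lower at that level, and of the 6131 features without one, 66 were higher and 328 lower. Fitted with the slide as a block, 0 features passed as well, with 2437 at an unadjusted p under 0.05. The counts were not 0 in 4 other settings. A robust estimate of the variance passed 1 feature higher and 5 lower, which were AT1G26250 and the 5 lower genes named above, and unscaled signals passed 41 higher and 4 lower. On the 4 arrays of slide 1 alone, a choice made after seeing the data, 12 features were higher and 12 lower. Leaving out control replicate 3 passed 1 feature in each direction. In simulated data with the spread of these arrays, the same test recovered 48.8% of genes changed by 0.5 on the log2 scale, 80.0% of those changed by 1 and 98.4% of those changed by 2. Each simulated round held 200 changed genes, which eases the adjusted threshold for each of them. The shares thus do not give the chance of finding a change where few genes changed.

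Most measured genes differed little. The median difference of all features was -0.00088, 81.1% of features lay within 0.2 of 0 on the log2 scale, and 69 features, 44 of them genes with an ID, differed at least 2-fold. In 12% of features the 3 ethanol arrays did not overlap the 3 control arrays, where chance gives 10%. The differences measured on the 2 slides were unrelated to each other across features, with a Pearson correlation of -0.05 and a Spearman correlation of 0.04 across 27459 features, which are not independent replicates.

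**Figure D1:**
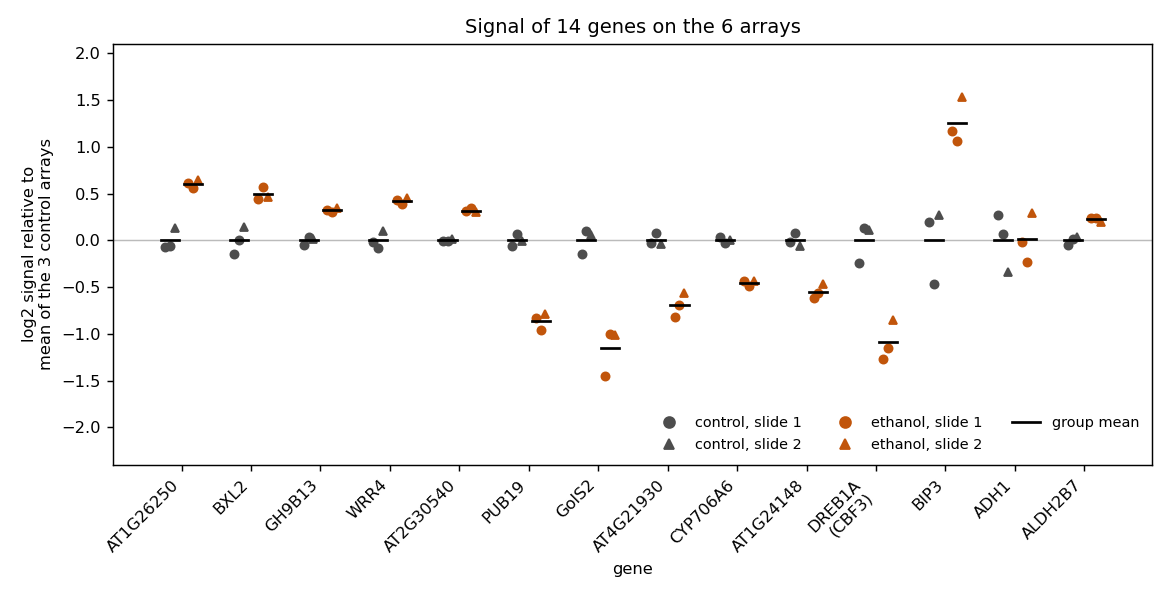
Signal of 14 genes on the 6 arrays, as log2 relative to the mean of the 3 control arrays (vertical axis). The genes are the 10 picked by the smallest p in each direction, and DREB1A (CBF3), BIP3, ADH1 and ALDH2B7. Each array has 1 point (circles slide 1, triangles slide 2), and bars lie at group means. GolS2 lies 1.16 lower in ethanol-grown plants, BIP3 1.25 higher, and ADH1 differs by 0.01.

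Genes that handle ethanol itself differed little over the 6 arrays, and several differed in opposite directions on the 2 slides. ADH1 (AT1G77120), the alcohol dehydrogenase that oxidises ethanol to acetaldehyde, differed by 0.01 ± 0.17 on the log2 scale, with -0.30 on slide 1 and 0.64 on slide 2. The largest difference among the 13 measured members of the ethanol and fermentation list was in ALDH2B7 (AT1G23800), a mitochondrial aldehyde dehydrogenase, at 0.22 ± 0.06 with all 3 ethanol arrays above the control arrays. It did not pass over all genes (adjusted p = 0.492, limma) and was the 1 member that passed when adjusted over the list alone. The aldehyde dehydrogenases ALDH2B4 and ALDH2C4 differed by 0.06 and 0.09, and the acetyl-CoA synthetases ACS and AAE7 (ACN1 in the list) by 0.01 and -0.02. The pyruvate decarboxylases PDC1 (AT4G33070), PDC2 and PDC3 differed by 0.09, -0.17 and 0.03. On slides 1 and 2 PDC1 was at -0.13 and 0.53, PDC2 at -0.42 and 0.32, and SUS4 at -0.26 and 0.46. The lactate dehydrogenase LDH1 (AT4G17260) differed by 0.06, HOT5 by 0.04, and the sucrose synthases SUS4 and SUS1 by -0.02 and 0.00. SUS1 was well above background on 1 of the 3 control arrays. The list as a whole had a mean difference of 0.03 (camera, adjusted p = 0.168), with -0.06 on slide 1 and 0.22 on slide 2. It passed without ethanol replicate 2 (0.07, adjusted p = 0.043) and with no filter (0.02, adjusted p = 0.048). It also passed with the root index of each array, root marker mean minus photosynthesis mean, as a covariate (0.15, adjusted p = 0.0020), a choice made after seeing the data. Relative to the control mean the index was 0.43, 0.46 and 0.04 on ethanol replicates 1, 2 and 3. Adjusting for it thus weighs the comparison toward ethanol replicate 3, which lay on slide 2. The mean of the ethanol list was -0.02 without control replicate 3 and -0.01 without ethanol replicate 3. The core low-oxygen genes, which include ADH1 and PDC1, had a mean of -0.02 over 28 members (adjusted p = 0.845, and adjusted p = 0.959 with an estimated correlation of 0.55). The calls below took the preset correlation of 0.01, which treats these genes as nearly independent. Their list passed as lower without control replicate 3 (-0.14, adjusted p = 0.00076) or ethanol replicate 3 (-0.12, adjusted p = 0.0067) and on slide 1 alone (-0.24, adjusted p = 1.9e-11). It passed as higher with the root index as a covariate (0.27, adjusted p = 5.3e-10), and its mean was above 0 without control replicate 1 (0.05), control replicate 2 (0.04) or ethanol replicate 2 (0.06). Its members with the smallest p were PHI-1 at 0.46 and PFK6 at 0.15.

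Gene lists fixed before the data were examined were tested as sets with limma's camera, which compares a list with all other tested features. Among these were 6131 features without a gene ID, with a median difference of -0.060 against 0.008 for genes with an ID. A comparison with genes that have an ID alone was not run. Of 28 lists tested, 8 were higher and 7 lower in ethanol-grown plants at an adjusted p under 0.05 with the preset inter-gene correlation of 0.01. With an inter-gene correlation estimated from these arrays, 0 lists passed, and the 15 calls had adjusted p-values between 0.415 and 0.655. By fry, which asks whether a list's genes move one way on balance, 0 lists passed (smallest adjusted p = 0.418). With the slide as a block, 9 lists were higher and 7 lower, and the 15 lists remained called. Of those 15 lists, 9 had the same direction on both slides and 6 opposite directions. With normexp background correction the split was 9 higher and 3 lower. Splits of the 6 arrays that mixed the groups called between 5 and 15 lists with the preset correlation. No member of any list passed over all genes.

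Photosynthesis genes were lower and cell division genes higher, both by small amounts and on both slides. All 32 measured photosystem, light-harvesting and Calvin cycle genes were lower, with a mean of -0.13 (adjusted p = 3.3e-07, and adjusted p = 0.415 with an estimated correlation) and means of -0.14 on slide 1 and -0.10 on slide 2. The size depended on the scaling, with means of -0.06 with quantile scaling (adjusted p = 0.0058), -0.05 with normexp correction and quantile scaling, -0.08 with median scaling and -0.07 in the authors' value table. Unscaled, the list was at 0.06 where the median of all features was at 0.19. CAB3 differed by -0.20, LHCB2.3 by -0.18, RBCS3B by -0.18 and PSAD-1 by -0.17, and 0 members passed adjusted over the list alone. Of 25 cell cycle and DNA replication genes, 21 were higher, with a mean of 0.09 (adjusted p = 0.00012, and adjusted p = 0.415 with an estimated correlation), 0.10 on slide 1 and 0.07 on slide 2. The list's mean on each ethanol array lay above that on each control array. PLE differed by 0.27, CYCB1;4 by 0.23, HIK by 0.15 and CDKB1;1 by 0.12, and 0 members passed adjusted over the list alone. Root markers were higher as well over all 6 arrays. Their mean was 0.18 over 22 genes, of which 19 were higher (adjusted p = 7.1e-06, and adjusted p = 0.443 with an estimated correlation), with MYB36 at 0.25, CASP4 at 0.38, SHV2 (COBL9) at 0.41 and EXPA18 at 0.30. The root mean was 0.35 on slide 1 and -0.16 on slide 2, and 0.28 without ethanol replicate 3. No root marker passed adjusted over the list alone.

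Flavonoid and anthocyanin genes and sugar-starvation genes were higher. In the flavonoid list 17 of 19 measured genes were higher, with a mean of 0.27 (adjusted p = 2.7e-06, and adjusted p = 0.415 with an estimated correlation). Flavanone 3-hydroxylase F3H differed by 0.34 ± 0.08 and was the 1 member that passed adjusted over the list alone. The anthocyanin enzymes DFR and LDOX differed by 0.65 ± 0.23 and 0.67 ± 0.24, and chalcone synthase TT4 (CHS) by 0.25 ± 0.08. In the sugar-starvation list 19 of 21 genes were higher, with a mean of 0.23 (adjusted p = 2.7e-06, and adjusted p = 0.415 with an estimated correlation). DIN10, a raffinose synthase family gene, differed by 0.37 ± 0.07 and was the 1 member that passed adjusted over the list alone. BT2 differed by 0.37 ± 0.11, and the trehalose phosphate synthase family genes TPS9 and TPS10 by 0.20 ± 0.08 and 0.18 ± 0.07. Most of both shifts came from slide 2. The flavonoid mean was 0.08 on slide 1 and 0.65 on slide 2, where control replicate 3 had the lowest value of the 6 arrays, and the sugar-starvation mean was 0.06 and 0.57. Without control replicate 3 the means were 0.14 and 0.14, and without ethanol replicate 3 the sugar-starvation mean was 0.15, and in these fits both lists were still called. Root markers differed by 0.35 on slide 1 and -0.16 on slide 2, and with the root index as a covariate the flavonoid mean was 0.49 and the sugar-starvation mean 0.47.

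**Figure D2:**
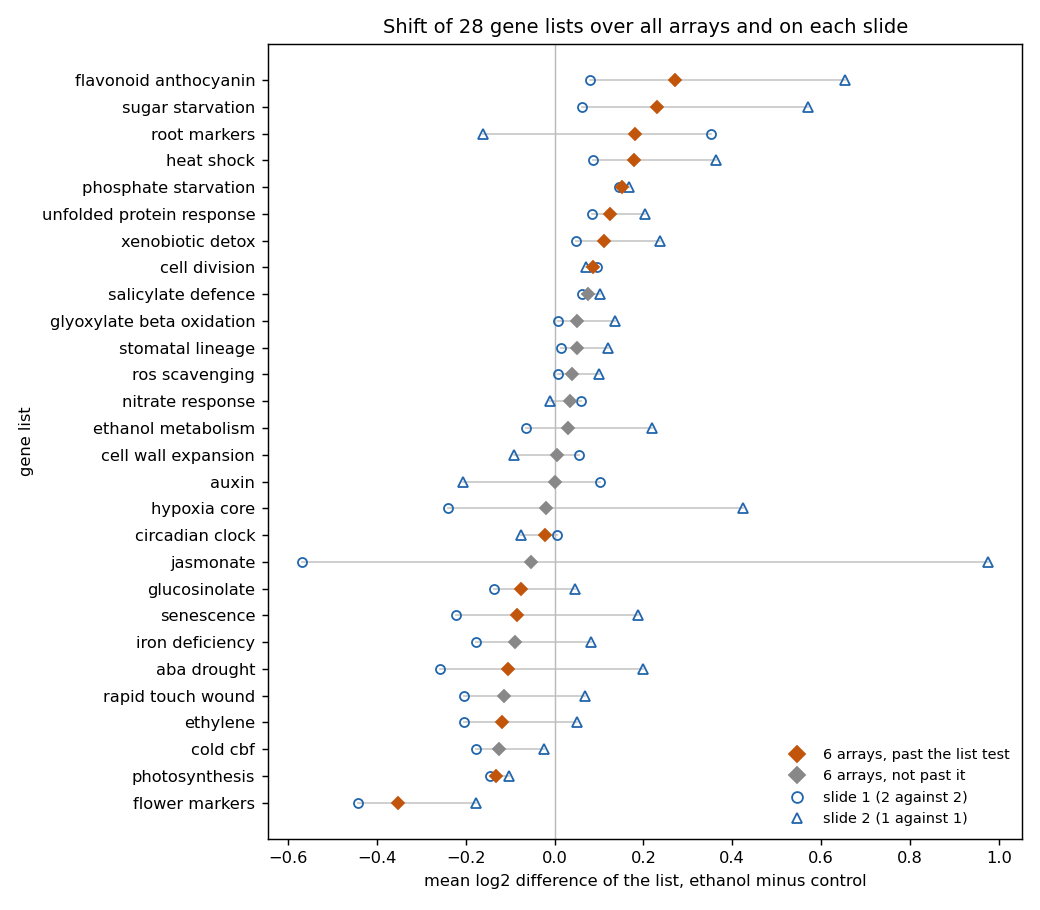
Mean log2 difference, ethanol minus control, of each of the 28 tested gene lists (horizontal axis), over the 6 arrays (diamonds, coloured where the list passed with the preset correlation), on slide 1 (circles) and on slide 2 (triangles). The photosynthesis list lies at -0.14 and -0.10 on the 2 slides, and the jasmonate list at -0.57 and 0.98.

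The drought and cold genes with the smallest p-values were lower in ethanol-grown plants, while the rest of those lists went both ways. In the abscisic acid and water-deficit list, 14 of 25 genes were lower and 11 higher, with a mean of -0.11 (adjusted p = 0.022, and adjusted p = 0.562 with an estimated correlation). P5CS1, which makes proline, differed by -0.55 ± 0.07, NCED3, which makes abscisic acid, by -0.57 ± 0.13, and the phosphatases HAI2 and HAB1 of abscisic acid signalling by -0.89 ± 0.24 and -0.33 ± 0.10. HAI2 was at -1.27 on slide 1 and -0.13 on slide 2. Adjusted over the list alone 4 members passed, all lower. The list's mean was -0.26 on slide 1 and 0.20 on slide 2, and its call was lost without control replicate 2 (-0.06, adjusted p = 0.234) or ethanol replicate 1 (-0.04, adjusted p = 0.212). The call was also lost with normexp correction (adjusted p = 0.055), with no filter (adjusted p = 0.122) and with no variance trend (adjusted p = 0.077), and the mean was -0.06 without ethanol replicate 2 and -0.22 without ethanol replicate 3. P5CS1 was at -0.57 and -0.51 on the 2 slides and NCED3 at -0.50 and -0.71. The cold list did not pass (adjusted p = 0.087). It passed as lower without control replicate 1 (-0.17, adjusted p = 0.016), without ethanol replicate 3 (-0.20, adjusted p = 0.011), without members shared with other lists (-0.21, adjusted p = 0.032), on slide 1 alone (-0.18, adjusted p = 0.043), with median scaling (adjusted p = 0.020) and unscaled (adjusted p = 0.014), and its mean was -0.07 without ethanol replicate 1 (adjusted p = 0.471) and 0.01 with the root index as a covariate (adjusted p = 0.900). Its mean was -0.13 and its median 0.04 over 13 genes, so they differ in sign, and the test pointed lower. DREB1A (CBF3) and CBF2, transcription factors of the cold response, differed by -1.09 ± 0.15 and -0.57 ± 0.10, and 3 members passed adjusted over the list alone. Over the settings DREB1A lay between -1.21 and -0.61 and CBF2 between -0.64 and -0.35. By fry's test for change in either direction the drought list had an adjusted p of 0.011 and the cold list one of 0.0042. Root markers differed by 0.35 on slide 1, where the drought list was lower, and by -0.16 on slide 2, where it was higher.

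Of 17 circadian clock genes, 11 were lower, with a mean of -0.02 and a median of -0.05 (adjusted p = 0.035, and adjusted p = 0.415 with an estimated correlation). PRR9, a clock repressor of the morning, differed by -0.57 ± 0.10, CDF1 by -0.41 ± 0.10, CCA1 by -0.13 ± 0.05 and RVE1 by -0.16 ± 0.08. PRR9 and CDF1 passed adjusted over the list alone. BOA had the largest difference of the list and was higher, at 1.16 ± 0.62, which came from ethanol replicate 2, at -0.97 relative to the 75th percentile where the other 5 arrays lay between -4.06 and -3.50. The call was lost without control replicate 2 (-0.01, adjusted p = 0.095), ethanol replicate 1 (0.01, adjusted p = 0.135) or ethanol replicate 3 (0.01, adjusted p = 0.118), and the mean was -0.09 without ethanol replicate 2. It was also lost with median scaling (0.03, adjusted p = 0.122), unscaled (adjusted p = 0.577), with normexp correction (adjusted p = 0.178), with no filter (adjusted p = 0.102) and with no variance trend (adjusted p = 0.067). The list's mean was 0.01 on slide 1 and -0.08 on slide 2.

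Stress and detoxification lists were higher. BIP3 (AT1G09080), an endoplasmic reticulum chaperone that the unfolded protein response induces, had the largest difference of the named genes that were higher, at 1.25 ± 0.22 or 2.38-fold, with 1.25 on slide 1 and 1.26 on slide 2. Its size depended on the background correction, at 0.59 with normexp correction, 0.66 with normexp correction and quantile scaling and 0.89 in the authors' value table. It did not pass over all genes (adjusted p = 0.247, limma), passed with unscaled signals (1.45, adjusted p = 0.00010), and was the 1 member of its list that passed adjusted over the list alone. In that list 20 of 24 genes were higher, with a mean of 0.12 (adjusted p = 0.0029, and adjusted p = 0.508 with an estimated correlation), and without BIP3 the mean of the 23 others was 0.07, with 19 of them higher and 0 at an unadjusted p under 0.05. ERDJ3B was at 0.13, BZIP60 at 0.10 and CRT1b (AT1G09210) at 0.15. Heat shock genes had a mean of 0.18 over 20 genes (adjusted p = 0.016, and adjusted p = 0.648 with an estimated correlation), with HSFA7A at 0.24, HSP17.8 (AT1G07400) at 0.40, HSP15.7 (AT5G37670) at 0.24 and ROF1 at 0.12. For HSP70 the probe used gave 0.07, while 9 of its 11 exon probes were lower, with a mean of -0.15. Most exon probes of HSFA7A (3 of 4), HSFA2 (4 of 5) and HSP90.1 (10 of 14) were higher, as were the probes used. For DREB2A all 7 were lower, as was the probe used. Glutathione transferase and xenobiotic response genes had a mean of 0.11 over 18 genes (adjusted p = 0.0029, and adjusted p = 0.415 with an estimated correlation), with GSTU24 at 0.28, GSTU25 at 0.25, GSTF8 at 0.15 and CYP81D8 at 0.22. Phosphate-starvation genes had a mean of 0.15 over 17 genes (adjusted p = 0.015, and adjusted p = 0.655 with an estimated correlation), with PHT1;4 at 0.32, PHT1;1 at 0.25, AT5G03545 at 0.33 and PS2 at 0.42. In the heat shock, xenobiotic and phosphate lists 0 members passed adjusted over the list alone, and root markers were higher over the same arrays by 0.18. These 4 lists were higher on both slides. Without ethanol replicate 1 all 4 calls were lost, with means of 0.10 for the unfolded protein response, 0.13 for heat shock, 0.07 for xenobiotic response and -0.01 for phosphate starvation. The heat shock call was also lost without control replicate 1 (0.10) or ethanol replicate 3 (0.04), and the phosphate call without control replicate 2 (0.03) or control replicate 3 (0.14). The phosphate mean was 0.29 without control replicate 1 and 0.31 without ethanol replicate 2, the heat shock mean 0.36 without ethanol replicate 2 and 0.10 with normexp correction, and the xenobiotic mean 0.07 without control replicate 3 and 0.17 without ethanol replicate 2. With the 4 arrays of slide 1 alone, the unfolded protein response, heat shock and xenobiotic lists did not pass (adjusted p = 0.156, 0.457 and 0.081). With the root index as a covariate these 3 lists were at 0.19, 0.45 and 0.19, and the phosphate call was lost (0.12, adjusted p = 0.267).

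Senescence, glucosinolate, ethylene and flower lists were lower. Of 12 senescence genes 10 were lower, with a mean of -0.09 and a median of -0.14 (adjusted p = 0.0029, and adjusted p = 0.415 with an estimated correlation). SAG29 differed by -0.45, SAG101 by -0.52, NYC1 by -0.21 and the transcription factor NAP by -0.21, and 3 members passed adjusted over the list alone. Of 21 genes of glucosinolate synthesis, a group of defence compounds, 17 were lower, with a mean of -0.08 (adjusted p = 0.0029, and adjusted p = 0.562 with an estimated correlation). The regulator MYB29 differed by -0.28 and was the 1 member that passed adjusted over the list alone, and CYP79F1, SOT17 and SOT18 differed by -0.28, -0.20 and -0.15. Of 15 ethylene genes 14 were lower, with a mean of -0.12 (adjusted p = 0.023, and adjusted p = 0.562 with an estimated correlation), among them ERF1 at -0.61, ERF2 at -0.47, ARL at -0.13 and EBF1 at -0.09. On slides 1 and 2 ERF1 was at -0.93 and 0.05, ERF2 at -0.71 and -0.0033, ARL at -0.19 and 0.01, and EBF1 at -0.09 on both. All 8 measured floral genes were lower, with a mean of -0.35 (adjusted p = 0.011, and adjusted p = 0.415 with an estimated correlation), among them SOC1 (AGL20) at -0.24, SEP1 at -0.53, FUL (AGL8) at -0.27 and AP3 at -0.91 with an SE of 0.62. AP3 was well above background on 2 of the 3 ethanol arrays. It lay at -5.85 on ethanol replicate 3 and at -4.10 and -3.39 on ethanol replicates 1 and 2, and its difference ran from -1.44 to -0.21 over the settings. In the ethylene and floral lists 0 members passed adjusted over the list alone. The senescence, glucosinolate and ethylene lists were lower on slide 1 at -0.22, -0.14 and -0.20 and higher on slide 2 at 0.19, 0.05 and 0.05, and the floral list was lower on both at -0.44 and -0.18. Root markers went the other way from the first 3 on both slides, at 0.35 and -0.16. With the root index as a covariate those 3 calls were lost, with means of 0.05, -0.02 and -0.04. Without control replicate 1 all 4 calls were lost, with means of -0.00025, -0.02, -0.06 and -0.18. The ethylene call was also lost without ethanol replicate 1 (-0.12) or ethanol replicate 2 (-0.10), the glucosinolate call without ethanol replicate 2 (-0.04), and the floral call without control replicate 2 (-0.30) or ethanol replicate 3 (-0.22). Without control replicate 3 the means were -0.19, -0.12, -0.18 and -0.58, and the senescence mean was -0.14 without ethanol replicate 1 and -0.0030 without ethanol replicate 2. With normexp correction the ethylene and glucosinolate calls were lost (adjusted p = 0.104 and 0.106), and unscaled the ethylene, glucosinolate and senescence calls (adjusted p = 0.073, 0.281 and 0.061). The ethylene call was also lost without members shared with other lists (-0.08, adjusted p = 0.061), and the floral call with no filter (-0.21, adjusted p = 0.168). The floral mean was -0.23 with normexp correction, -0.16 with normexp correction and quantile scaling and -0.20 in the authors' value table. The senescence mean was -0.21 without members shared with other lists and -0.16 with genes above background on all arrays alone.

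**Figure D3:**
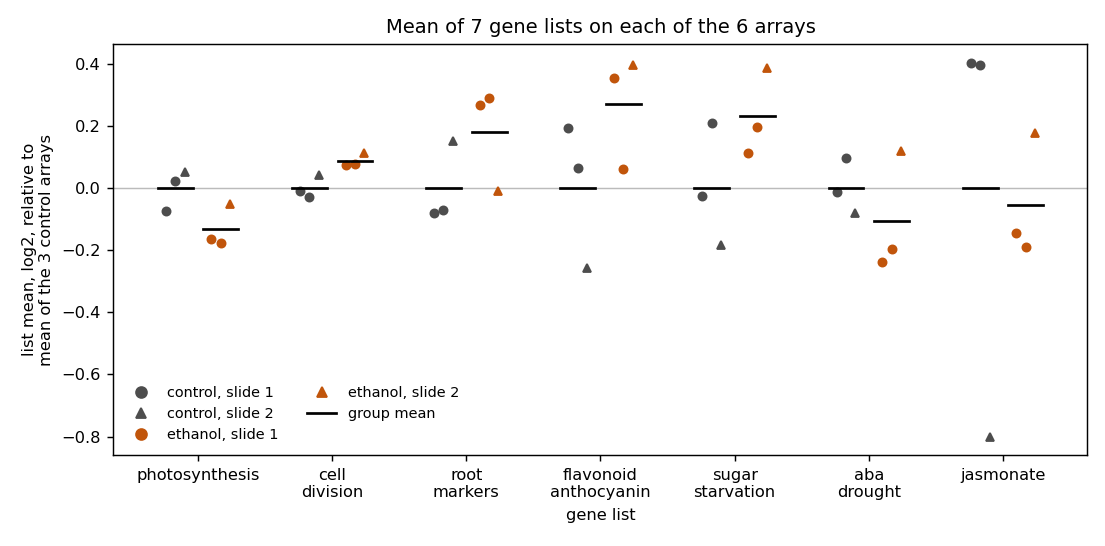
Mean of 7 gene lists on each array, as log2 relative to the mean of the 3 control arrays (vertical axis), with 1 point per array (circles slide 1, triangles slide 2) and bars at group means. The cell division list lies between 0.07 and 0.11 on the 3 ethanol arrays and between -0.03 and 0.04 on the 3 control arrays, and the jasmonate list spans 1.2 over the 6 arrays.

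The other lists did not pass. The touch and wound list had a mean of -0.11 (adjusted p = 0.134). It passed as lower without control replicate 3 (-0.23, adjusted p = 0.00055) or ethanol replicate 1 (-0.20, adjusted p = 0.0080), on slide 1 alone (-0.20, adjusted p = 0.0049), with median scaling (adjusted p = 0.014) and unscaled (adjusted p = 0.035), and its mean was -0.01 without control replicate 1 and -0.05 without ethanol replicate 2. In this list 3 of 17 members passed adjusted over the list alone, with CAF1a at -0.56 ± 0.09 and ERF105 (AT5G51190) at -0.68 ± 0.15. Cell wall expansion genes had a mean of 0.01 (adjusted p = 0.718) and went both ways, with the expansin EXPA1 at -0.33 ± 0.06 and XTH9 at 0.38 ± 0.09, the 2 members that passed adjusted over the list alone. In the jasmonate list (mean -0.05, adjusted p = 0.616) CYP94B3 differed by 0.50 and ERF1 by -0.61. By camera with an estimated correlation of 0.68 the jasmonate list had an adjusted p of 0.904 over the 6 arrays. Its calls in other settings took the preset 0.01, which treats its genes as nearly independent. The list passed as lower without control replicate 3 (-0.45) or ethanol replicate 3 (-0.17) and on slide 1 alone (-0.57, adjusted p = 1.2e-21). It passed as higher with the root index as a covariate (0.46, adjusted p = 5.0e-10), and its mean was above 0 without control replicate 1 (0.15), control replicate 2 (0.15) or ethanol replicate 2 (0.01). Genes of the glyoxylate cycle and beta-oxidation, through which acetate can be used, had a mean of 0.05 over 17 genes (adjusted p = 0.058, and adjusted p = 0.024 with the slide as a block). This list also passed with normexp correction (adjusted p = 0.015), with no filter (adjusted p = 0.0043), without members shared with other lists (adjusted p = 0.039) and with the root index as a covariate (0.11, adjusted p = 0.013), and its mean was 0.03 in the authors' value table (adjusted p = 0.358). Its members with the smallest p were PMDH2 at -0.19 and ACX2 at 0.11. Reactive oxygen scavenging genes had a mean of 0.04 (adjusted p = 0.366), with APX2 at 0.77 ± 0.31, which was well above background on 1 of the 3 control arrays, and MDAR2 at 0.14. Salicylate defence genes had a mean of 0.08 (adjusted p = 0.247), with NIMIN-2 at 0.25 and FMO1 at 0.18. The salicylate mean was -0.04 without ethanol replicate 1 and 0.01 without control replicate 2 or control replicate 3. Auxin genes had a mean of 0.00 (adjusted p = 0.681), with SAUR15 at 0.21 and DFL1 (GH3.6) at 0.23. Iron-deficiency genes had a mean of -0.09 (adjusted p = 0.634), with MYB10 at -0.24 and AT3G13610 at 0.18. Nitrate genes had a mean of 0.04 and a median of -0.01 (adjusted p = 0.616), with WR3 (NRT3.1) at 0.23 and NIR1 at -0.11. Stomatal lineage genes had a mean of 0.05 (adjusted p = 0.193), with ERL1 at 0.18 and OZS1 (SLAC1) at -0.22. Of the seed storage genes only OLEO4 was measured, at 0.20, and the list was not tested. Leaving out 1 array also made calls in 6 of these lists. Without ethanol replicate 2 the reactive oxygen (0.07), iron-deficiency (0.09), stomatal (0.11) and glyoxylate (0.07) lists passed as higher. Without control replicate 1 the salicylate (0.21) and glyoxylate (0.06) lists did so, and without ethanol replicate 3 the cell wall list (0.06), while the iron-deficiency list passed as lower (-0.20).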

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

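The settings with slide 1 alone, with the root index and with adjustment over gene IDs alone were chosen after the data were seen. No feature passed in either direction with quantile scaling, median scaling, normexp correction with either scaling, the authors' value table, the other filters, the mean of probes, every probe on its own, no variance trend, the slide block, adjustment over gene IDs alone, or a further limit of 2-fold. Unscaled signals, which move the median of all features by 0.19, gave 41 features higher and 4 lower, a robust variance 1 higher and 5 lower, and slide 1 alone 12 higher and 12 lower. An adjusted p under 0.1 gave 1 higher and 7 lower, and an unadjusted p under 0.01 gave 164 higher and 301 lower. Leaving out 1 array at a time gave between 0 and 1 in each direction, the 1 in each without control replicate 3. Of the genes named, 96 kept their sign in every setting other than unscaled signals, where the shift of all features changed the sign of 13, and 9 passed in at least 1 setting. Of the 5 genes with the smallest p in each direction, AT1G26250 had adjusted p-values between 0.023 and 0.697 over the settings and GolS2 between 0.0028 and 0.697, and both kept their direction.

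Of 8 lists higher and 7 lower, normexp correction gave 9 and 3, median scaling 8 and 8, no scaling 8 and 5, no variance trend 8 and 5, no filter 11 and 4, lists without shared members 9 and 7, and slide 1 alone 5 and 10. An estimated correlation gave 0 and 0, and fry gave 0 and 0. In simulated lists of independent genes the estimated correlation recovered a shift of 0.15 in 0 of 5 rounds. That does not tell how either test does where the genes of a list vary together. With the root index of each array as a covariate 12 lists were higher and 2 lower, and the drought list turned (0.15, adjusted p = 0.395). Root markers and photosynthesis genes make up the index, so both take the same value by construction (-0.061). The calls of the senescence (0.05), ethylene (-0.04), glucosinolate (-0.02) and phosphate (0.12) lists were lost with it as well. The ethanol (0.15), low-oxygen (0.27), jasmonate (0.46), reactive oxygen (0.10), glyoxylate (0.11) and stomatal (0.15) lists were called as higher with it. Relative to the control mean the index was 0.43, 0.46 and 0.04 on ethanol replicates 1, 2 and 3. Adjusting for it thus weighs each comparison toward ethanol replicate 3 on slide 2, so these calls do not show a response beyond a different share of root. For the other changes the cause was not tested. Leaving out 1 array at a time gave between 4 and 13 lists higher and between 4 and 10 lower. Without ethanol replicate 1 the phosphate-starvation list turned to -0.012 (adjusted p = 0.942), and without ethanol replicate 2 it was at 0.307. The photosynthesis, cell division, root, flavonoid and sugar-starvation lists stayed past the threshold without any 1 array. With the other scalings no called list changed its direction relative to the other features.

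Samples of the same replicate number in both groups shared a slide and a scan, and the labels do not say what else the number marks. Deviations from the group means correlated at 0.32, 0.06 and 0.10 between arrays of the same number, so each pair was positive but not each lay above 0.1. Between arrays of different numbers the values ran from -0.25 to 0.13, so a pairing is not settled. Control replicate 3 correlated better with ethanol replicate 2 (0.13) than with its own number. With the replicate block 0 features were higher and 0 lower, 2727 had an unadjusted p under 0.05, and 9 lists were higher and 7 lower, the glyoxylate and beta-oxidation list (adjusted p = 0.025) being the addition. SUS1, APX2 and AP3 were the genes named that were not well above background on all 6 arrays.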

Other observations

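The tests on BIP1 and BIP2, on the other chaperones, of the drought list with the root index, of the clock genes without BOA and of the gene families were chosen after the result was seen, and so was the measure of root marker classes over arrays. Every group of at least 10 measured genes that share the letters of a reference symbol, and each set of organelle-encoded genes of that size, was tested, 129 in all, and 5 were higher and 3 lower in ethanol-grown plants with the preset correlation. Arabinogalactan protein genes (AGP) were higher, 24 of 27 with a mean of 0.14 (camera, adjusted p = 1.9e-05), and so were 21 of 26 xyloglucan endotransglucosylase genes (XTH) with a mean of 0.14 (adjusted p = 0.0030), 16 of 20 RABA genes with 0.09, 12 of 14 fasciclin-like genes (FLA) with 0.12 and 9 of 11 TPS genes with 0.08. B-box genes (BBX), which include light signalling factors, were lower with a mean of -0.22 over 16 genes (adjusted p = 1.9e-05), ERF genes with -0.17 over 22 and HCF genes with -0.10 over 12. With an estimated correlation 0 of the 129 families passed (smallest adjusted p = 0.894). Of the 10 splits of the 6 arrays, 5 gave at least the 8 families of the real one, up to 15 in another split, and 10 splits are too few to give a share under 0.05.

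The jasmonate list varied more between arrays than any other tested list, and not by group. Its mean was 0.40 on control replicates 1 and 2, -0.80 on control replicate 3, -0.15 and -0.19 on ethanol replicates 1 and 2, and 0.18 on ethanol replicate 3. The difference between groups was thus -0.57 on slide 1 and 0.98 on slide 2. The low-oxygen list went the same way, at -0.24 and 0.42, and so did ADH1, at -0.30 and 0.64. On slide 2 each group had 1 array.

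Exon probes beside a gene's own probe were measured for 12 genes. Those of NCED3 (6 probes, -0.51 to -0.82), DREB1A (3 probes, -0.59 to -1.03) and RD20 (7 probes, -0.23 to -0.41) were lower, as were the probes used for these genes. For HSP70 and Hsp70-2 the probe used gave 0.07 in both, while 9 of 11 and 10 of 12 exon probes were lower, with means of -0.15 and -0.17. Most exon probes were higher, as was the probe used, for LTI65 (RD29B in the drought list, 3 of 4), HSFA7A (3 of 4), HSFA2 (4 of 5), HSFA3 (4 of 6) and HSP90.1 (10 of 14). Those of DREB2A (7 of 7) and HSP81-3 (9 of 12) were mostly lower, as were the probes used.

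The count of 1834 features at an unadjusted p under 0.05 was reached or passed by 3 of the 10 splits of the 6 arrays, the real one included, with 2541 in the highest of the others. That split set control replicates 1 and 2 with ethanol replicate 1 against the rest. The third, with 2038, set control replicate 1 with ethanol replicates 1 and 2 against the rest, and in both the 2 arrays of slide 2 fell on 1 side. They did so in 2 other splits as well, which gave 1015 and 1372. For the 15 gene lists called, 2 of the 10 splits gave as many. Every split that mixed the groups called lists as well, from 5 in the lowest to 15 in the highest. In both cases 10 splits are too few to give a share under 0.05. With the slide as a block, 0 features and 16 lists passed.

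Root markers were higher and photosynthesis genes lower over the 6 arrays, and a larger share of root in the ethanol-grown plants is a candidate explanation. The root index, root marker mean minus photosynthesis mean, was 0.31 higher in the ethanol group (exact permutation test, two-sided p = 0.2, the smallest possible being 0.1), but relative to the control mean it was 0.04 on ethanol replicate 3 and 0.10 on control replicate 3. The test set beforehand took it that a larger share raises all root markers alike, which holds only if all are equally confined to root. How far each class is confined to root was not measured, so a gap between classes cannot decide the question. The bound, that no 2 classes differ by more than 2 standard errors, was broken over genes. Root beta-glucosidases and aquaporins (0.06) lay 4.11 standard errors below endodermis markers (0.29), with root hair markers at 0.28. Over genes was the wrong measure, because root markers vary together from array to array (estimated inter-gene correlation 0.41), and over arrays, a measure taken up only after that outcome, the gap was 1.85 standard errors (exact permutation test, p = 0.2). The arrays thus leave a larger share of root open, as they do a response of the plants to ethanol. The photosynthesis part of the index also depended on the scaling, with a list mean of -0.13 in the main fit and -0.06 with quantile scaling. How much of that part comes from scaling was not tested.

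The lower drought and abscisic acid list might come from harvest later in the day or from a different share of root. Clock genes that rise after the collection time were on average 0.37 ± 0.19 (SE over genes) above those that fall after it, with medians of 0.04 and -0.15, which is in the direction of a later harvest but within 2 standard errors, and without BOA, which 1 array carried, the gap was 0.20 ± 0.10 with a rising median of 0.01, which at 2.02 standard errors passes the bound set for a later harvest, in a test chosen afterwards. The medians of root markers and photosynthesis genes lay 0.35 apart, as a different share of root needs, but with the root index as a covariate the list's mean went from -0.11 to 0.15 (adjusted p = 0.395), which neither keeps the shift nor brings it close to 0. The wording of the root test was revised after the medians had been seen. Both explanations, and a response to ethanol, stay open.

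BIP3 was the named gene with the largest higher value. The bound set against a signal near background was met, with its probe well above background on 6 of the 6 arrays. That bound decides little, since 25241 of the 27459 tested features met it. The difference of BIP3 was 0.59 with normexp correction, so how far background bears on its size stays open. A probe shared with BIP1 and BIP2 is argued against by their differences. These were 0.09 ± 0.08 for BIP1, which is 1.17 standard errors from 0, and 0.00 ± 0.08 for BIP2. A general rise of endoplasmic reticulum chaperones was to be ruled out if none of the 23 other list members had an unadjusted p under 0.05, and 0 had. That bound was the wrong one, since a p over a threshold does not show that values did not differ, and their mean was 0.075 ± 0.025 (SE over genes) with 19 higher. This SE takes the genes as independent, while genes of the list vary together (estimated inter-gene correlation 0.21). The list with BIP3 was at 0.17, 0.01 and 0.19 on ethanol replicates 1, 2 and 3, and between -0.02 and 0.03 on the control arrays. A general rise of these chaperones could be a part of the pattern and stays open, as does a response to ethanol, and BIP3 did not pass the test over all genes.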
